A study of Homo sapiens with 2 samples.

How the data were processed

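Total RNA of H1299 cells was extracted with Trizol, labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols, with 1 array for cells with p53 and 1 for the negative control. The deposited values are log2 intensities, 1 per probe set and array, summarised by the authors with robust multi-array average (RMA), per the submitters' processing notes. The software, its version, the probe set definition and the genome build are not given in the sources used here. The log2 scale was inferred from the values, which ran from 1.48 to 14.68 in the p53 array and from 1.41 to 14.68 in the control array. The sorted values of the 2 arrays differed by a median of 0.0096 and by at most 0.192, so the 2 distributions had been made nearly equal before deposition. A shift of total RNA per cell between the conditions would be removed by such a step and cannot be read from these values. Because an array gives no counts, the number of arrays, 1 per group, limits the precision. Of the probe sets, 35.9% held exactly the same value in both arrays.

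Probe sets were named through GEO's platform annotation, in which 19460 of the 33297 probe sets had 1 gene symbol, 1754 had several and 12083 had none in the table used here. Symbols were updated through the gene identifier to a current RefSeq gene table, which was also used to match older names of list members. Probe sets with several symbols or none were left out of the gene results. Some list members, and 1 gene planned as a separate result, are not reported here, so counts of list members refer to those measured. Where a gene had several probe sets (769 of 18417 genes), the one with the highest mean of the 2 arrays was used. No coordinates are given, since the files name no genome build.

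The difference of each gene was its log2 value with p53 minus that in the control. Genes were kept where the higher of the 2 arrays was at or above the median of all probe sets over both arrays, 7.38, which left 11436 genes. A gene was called higher or lower when the difference was at least 2-fold, a rule of size and not a test. For each of 24 gene lists the median difference of all measured members was compared with 10000 random lists of the same size, drawn from all 18417 genes in 20 bins of mean intensity. The position of the median among the random lists describes these 2 arrays and is not a test of the conditions, since genes are not replicates. The lists came from general knowledge of p53 targets and other pathways and several share members. Genes named in the text were those of the 5hmC enzymes TET1, TET2, TET3 and TDG, CDKN1A, MDM2, the 15 kept genes with the largest difference in each direction, and up to 4 kept members per list with the largest absolute difference. The lists, this rule, the thresholds and the alternatives were fixed before the data were examined. Other names are marked where they occur.

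On simulated data with normal noise of the observed spread over 11436 genes, the 2-fold rule called 86 of 100 genes changed by 1.5 on the log2 scale and 100 of 100 changed by 3, together with 2.23% of the unchanged genes. That spread, 0.43, was estimated from the median absolute deviation of the differences between the 2 arrays. It thus includes changes with p53 and is not a replicate error. The shares called follow from it, and 2.23% is not a rate of false calls in these data. Of 40 simulated lists of 20 genes without a shift, 40 lay inside the central 95% of random lists, and 40 of 40 lists shifted by 1 lay above it. The simulated differences were independent between genes, held no equal values and covered kept genes only, and a shift of 1 is large against 0.43. This check of the procedure therefore does not show how the list percentiles behave in these data. The alternatives were no filter, a filter at the 75th percentile (9.01), thresholds of 1.5-fold and 3-fold, centring of the differences on their median, removal of a lowess trend on intensity (span 0.3), the mean over probe sets of a gene, counting per probe set, quantile normalization of the deposited columns, and an offset of 32 before log2. For the lists they also included the mean in place of the median and members of 1 list only. A list value was taken as moved when it shifted by more than the standard deviation of its random lists, and a count when it changed by more than 1.5 times. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, with figures drawn in matplotlib 3.10.9.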

Results

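Gene expression was measured in H1299 cells, a human non-small cell lung carcinoma line that lacks p53, the transcription factor that responds to DNA damage and other stress. The design compared cells given p53 with cells of a negative control, and the series concerns p53 and 5-hydroxymethylcytosine (5hmC), an oxidised form of methylated cytosine, in gene regulation. How p53 was introduced, and for how long, is not given in the sources used here. Total RNA was hybridised to 1 Affymetrix array per group, so the data comprise 2 arrays with 33297 probe sets each. The median log2 intensity was 7.38 in the p53 array and 7.38 in the negative control array. There are no replicates. No difference below carries a p-value or a replicate error, and every difference describes these 2 arrays. Differences are log2 intensity in the p53 array minus log2 intensity in the negative control array.

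Lists of known p53 target genes were higher with p53, and lists of DNA replication and mitosis genes were lower. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, had a log2 intensity of 12.66 with p53 and 9.18 in the control, an 11.2-fold difference. MDM2, the ubiquitin ligase that degrades p53, stood at 13.59 with p53 and 10.87 in the control, a 6.55-fold difference. Of the 11436 genes kept by the intensity filter, 939 were at least 2-fold higher with p53 (8.21%) and 662 were at least 2-fold lower (5.79%). At a threshold of 1.5-fold the balance turned, with 1642 genes higher and 1777 lower. The higher genes reached further: 62 genes were at least 8-fold higher and 1 gene was at least 8-fold lower.

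The 15 largest positive differences ran from 4.11 to 5.62 on the log2 scale. CLCA2, a member of the calcium-activated chloride channel regulator family, was the highest at 10.45 with p53 against 4.83 in the control, a 49.2-fold difference. RNF144B, an E3 ubiquitin ligase, followed at 42.6-fold. The cysteine protease gene CTSH was 35.8-fold higher, and CYFIP2, a component of the WAVE actin regulatory complex, was 32.5-fold higher. FAM13C was 26.3-fold, SELENOP, which encodes a selenium transport protein, 24.6-fold, and GDF9 23.8-fold higher. LAMP3, a lysosomal membrane protein gene, was 23.6-fold higher, F2RL2, a thrombin receptor gene, 22.0-fold, and VCAN, which encodes the matrix proteoglycan versican, 20.3-fold. The remaining 5 were the phosphodiesterase gene PDE3A (18.5-fold), TP53I3, an oxidoreductase gene induced by p53 (18.2-fold), the phospholipid transfer protein gene PLTP (17.4-fold), TP53INP1, a nuclear protein gene induced by p53 (17.3-fold), and ID2, an inhibitor of helix-loop-helix transcription factors (17.3-fold). The control values of these 15 genes had a median of 6.80, below the filter level of 7.38, so the folds of many of them rest on a dim control signal. Detection calls were not used here. Where a control value lay below 5.97, the 25th percentile of all probe sets, the difference was also taken from that level, a floor chosen after the data were seen. From this floor CLCA2 was 22.3-fold higher, F2RL2 21.2-fold, PDE3A 17.7-fold and SELENOP 12.5-fold, so the exact folds and ranks of these 4 are not fixed.

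The 15 largest negative differences ran from -3.01 to -2.53. HJURP, the chaperone of the centromeric histone, was the lowest, at 8.13 with p53 against 11.14 in the control, an 8.08-fold lower level. The replication licensing gene CDC6 was 7.88-fold lower, FAM111B 7.34-fold lower, and the homologous recombination genes RAD51AP1 and XRCC2 were 7.13-fold and 6.97-fold lower. NUF2 and SPC25, both of the NDC80 kinetochore complex, were 6.91-fold and 6.02-fold lower. DTL, a substrate receptor of a replication-coupled ubiquitin ligase, was 6.70-fold lower, the spindle checkpoint kinase gene TTK 6.63-fold, and the cyclin gene CCNE2 6.36-fold. PLK4, the kinase of centriole duplication, FBXO5, an inhibitor of the anaphase-promoting complex, and the mitotic kinesin gene KIF23 were 6.31-fold, 5.98-fold and 5.96-fold lower. The last of the 15 were the histone genes H1-5 (5.91-fold) and H2BC14 (5.79-fold), which belong to families of near-identical copies, so that their probe sets can read more than 1 gene.

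**Figure D1:**
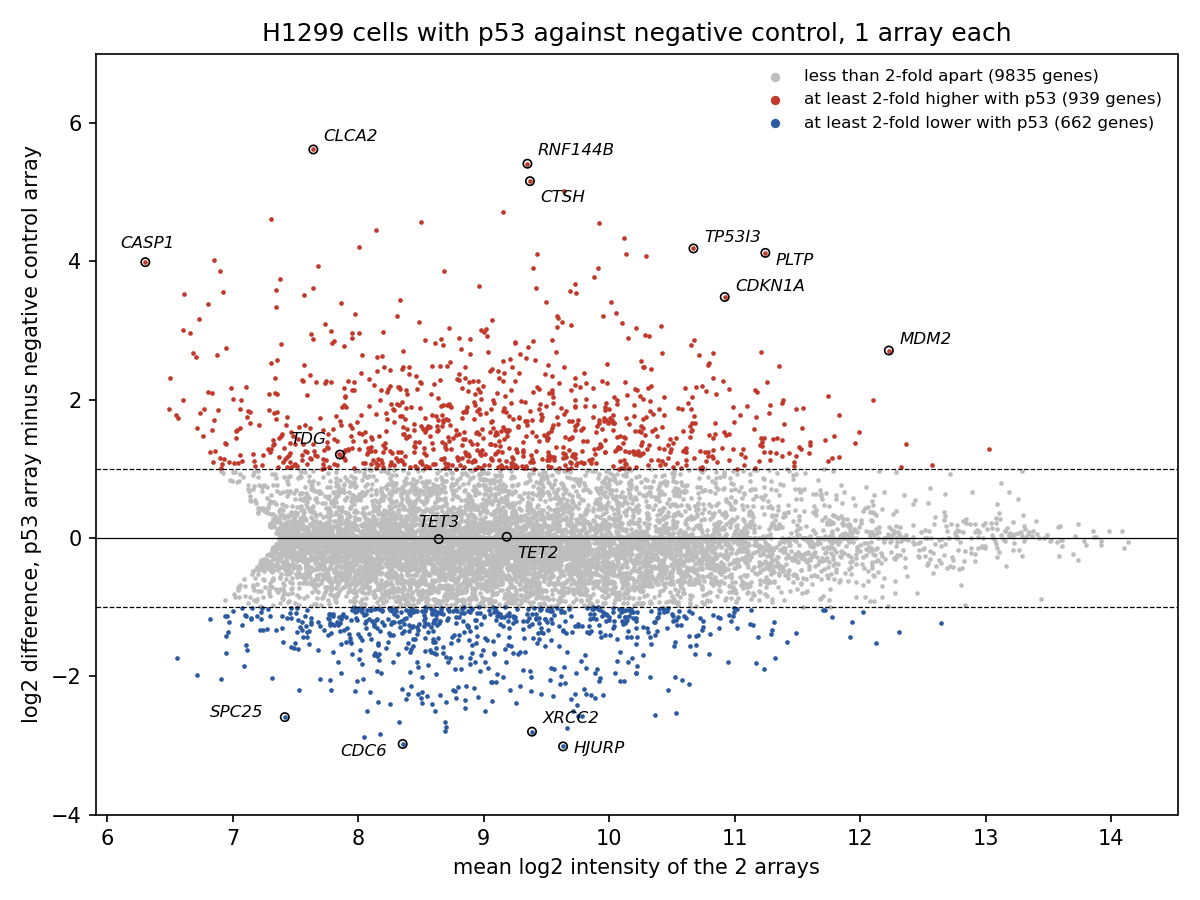
Each point is one of the 11436 kept genes, with the mean log2 intensity of the 2 arrays on the horizontal axis and the log2 difference, p53 minus negative control, on the vertical axis; dashed lines mark 2-fold. The 939 genes at least 2-fold higher reach 5.62 at CLCA2, whereas the 662 genes at least 2-fold lower reach -3.01 at HJURP, and TET2 and TET3 lie at 0.02 and -0.02.

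The fixed lists of p53 targets had medians above 0 in each of the 6 functional classes. Among 14 measured targets of cell cycle arrest, 8 were at least 2-fold higher, 1 was lower and 5 were neither, with a median difference of 1.66. The largest differences in this class were those of SESN1 (3.77), a stress-responsive regulator of TOR signalling, CDKN1A (3.49), PLK3 (3.21) and ZMAT3 (2.47), a zinc finger RNA-binding protein gene. The 1 lower member, named after its value was seen, was GTSE1 (-1.22), a G2 and S phase gene. Among 25 targets of apoptosis, 15 were at least 2-fold higher and 1 was lower, with a median of 1.29. TP53I3 (4.19), TP53INP1 (4.11), CASP1 (3.99), which encodes the inflammatory caspase, and APAF1 (3.54), the scaffold of the apoptosome, had the largest differences of this class. CASP1 stood at 4.31 in the control, below the floor of 5.97, from which its difference was 2.33, less than that of APAF1. Its 1 lower member, also named after its value was seen, was STEAP3 (-1.01). Of 12 genes listed under negative feedback on p53, 7 were at least 2-fold higher and none was lower, with a median of 1.56. RNF144B (5.41), DNAI3 (3.86), an axonemal dynein subunit gene, ZNF385A (3.62) and MDM2 (2.71) had the largest differences of this list. Being on the list does not show a feedback role, which was not tested here for DNAI3 or any other member. DNAI3 stood at 4.97 in the control, and from the floor its difference was 2.86, less than that of ZNF385A. The feedback median depended on the members used. It was 1.02 over members kept by the mean of the 2 arrays and 1.89 without genes equal in both arrays. Both alternatives were chosen after seeing the data.

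Of 9 DNA repair targets, 4 were at least 2-fold higher, namely the translesion polymerase gene POLH (2.49), the ribonucleotide reductase subunit gene RRM2B (2.17), DDB2 (2.17) and XPC (1.25), the last 2 being damage sensors of nucleotide excision repair. FANCC (-1.15), named after its value was seen, was the 1 member at least 2-fold lower, and the median was 0.74. Among 19 targets of metabolism and autophagy, 11 were at least 2-fold higher and none was lower, with a median of 1.34. SESN1 (3.77), the autophagy regulator DRAM1 (2.92), the fructose bisphosphatase gene TIGAR (2.89) and the coenzyme A synthesis gene PANK1 (2.87) were the largest. Of 25 targets that encode secreted or membrane proteins, 13 were at least 2-fold higher and none was lower, with a median of 1.13. VCAN (4.34), the KIT ligand gene KITLG (3.58), the stress cytokine gene GDF15 (3.41) and the extracellular sulfatase gene SULF2 (3.24) had the largest differences of this list. KITLG stood at 5.56 in the control, and from the floor of 5.97 its difference was 3.17, less than those of GDF15 and SULF2. For 5 of these 6 lists the median lay above all of the 10000 random lists matched on intensity. That of the DNA repair list lay above 9985 of them.

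Genes of the cell cycle were lower with p53. Of 39 measured G2/M genes, 37 were at least 2-fold lower, none was higher, and the median was -2.07, a 4.19-fold lower level. NUF2 (-2.79), TTK (-2.73), KIF23 (-2.57) and SGO1 (-2.51), the protector of centromeric cohesion, had the largest differences. The 2 members that were not 2-fold lower, named after their values were seen, were KIF20A (-0.39) and PTTG1 (0.46). Of 37 DNA replication and G1/S genes, 26 were at least 2-fold lower and none was higher, with a median of -1.34. CDC6 (-2.98), CCNE2 (-2.67), the primase gene PRIM1 (-2.51) and the replicative helicase gene MCM3 (-2.33) were the lowest. Both medians lay below all 10000 matched random lists. Among 26 replication-dependent histone genes, 10 were at least 2-fold lower and none was higher, with a median of -0.33 that lay below 9989 random lists. Their median was -0.58 over the 22 kept members, and their mean was -0.64. H1-5 (-2.56), H2BC14 (-2.53), H3C2 (-2.05) and H2BC9 (-1.74) were the lowest of these.

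Genes of the enzymes that write and remove 5hmC relate to the other subject of the series. Only their transcripts were measured here, so the values do not tell the level of 5hmC, of these proteins or of their activity. The TET genes encode the dioxygenases that oxidise 5-methylcytosine to 5hmC, and their differences were -0.01 for TET1, 0.02 for TET2 and -0.02 for TET3. TET1 had log2 intensities of 7.19 and 7.20, below the filter level in both arrays, whereas TET2 stood at 9.19 and 9.18 and TET3 at 8.63 and 8.65. TDG, the glycosylase that excises the further oxidised forms, was 2.31-fold higher with p53, at 8.46 against 7.25. CXXC5, a CXXC zinc finger gene, was 3.09-fold higher. NEIL3, a glycosylase of oxidised bases, was 5.27-fold lower and UHRF2, a reader of modified cytosine, 2.18-fold lower, but UHRF2 was at -0.99, less than 2-fold, with the lowess trend removed. Of 25 genes of 5hmC and DNA demethylation, 2 were at least 2-fold higher, 3 were lower and 20 were neither, with a median of -0.09 inside the central 95% of random lists (-0.21 to 0.02). The remaining lower member, named after its value was seen, was the glycosylase gene MBD4 (-1.08).

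Among 14 genes of DNA methylation and methyl-CpG binding, 1 was at least 2-fold higher and 2 were lower, with a median of -0.21, inside the central 95% of random lists. DNMT1, the maintenance methyltransferase gene, was 2.28-fold lower, at 9.94 against 11.13. UHRF1, its cofactor at replicated DNA, had a difference of -2.11, while a second, dimmer probe set of the same gene gave -0.01. AHCY, the hydrolase of S-adenosylhomocysteine, was 2.35-fold higher, and ZBTB4, a methyl-CpG-binding repressor gene, had a difference of 0.86. Of 19 genes of the p53 family and its regulators, MDM2 was 2-fold or more higher and CHEK1 (-1.43), a checkpoint kinase gene, was 2-fold or more lower. PPP1R13L (0.70) and TP53BP1 (-0.64) followed, and the list median was 0.00.

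Stress and signalling lists were mixed. Of 14 heat shock genes, 3 were at least 2-fold higher, namely CRYAB (3.74), a small heat shock protein gene, BAG3 (1.24) and HSPA4L (1.23), and HSPB1 stood at 0.80. CRYAB stood at 5.51 in the control, and its difference from the floor of 5.97 was 3.28. The median of this list, 0.31, lay above 9962 of the random lists, but over members kept by the mean of the 2 arrays it was 0.19, just inside the central 95% (percentile 97.475), as CRYAB was then left out. Of 24 genes of the integrated stress and unfolded protein response, 5 were at least 2-fold higher and none was lower, with CHAC1 (2.66), DDIT3 (1.90), EDEM1 (1.87) and SESN2 (1.76) in front and a median of 0.01. Among 19 immediate early genes, 5 were at least 2-fold higher, led by NR4A1 (2.77), EGR1 (2.65) and JUNB (2.01), and 3 were lower, with MYC at -1.65. Their median was 0.00. Of 34 interferon-stimulated genes, 4 were at least 2-fold higher and 1 was lower. IFIT3 was 11.4-fold higher, IFIT1 3.37-fold and ISG15 2.98-fold higher, SAMD9 was 2.56-fold lower, and IFIH1 (1.29), named after its value was seen, was the remaining higher member. IFIT3 stood at 5.81 in the control, and from the floor of 5.97 it was 10.2-fold higher. Of 24 genes of NF-kappaB and inflammation, 2 were at least 2-fold higher, the prostaglandin synthase gene PTGS2 (2.08) and NFKB1 (1.19), while NFKBIZ stood at 0.92 and NFKBIA at 0.86. The medians of the interferon and NF-kappaB lists were 0.00 over all members. Equal values hold them there, as 11 of the 34 and 8 of the 24 members were equal in both arrays. The central 95% of their random lists ran from 0.00 to 0.00 and from -0.05 to 0.00, so these medians tell little. Over the 15 and 16 members above the filter the medians were 0.16 and 0.23, at the percentiles 98.98 and 98.57 of random lists drawn the same way. That filter reads the higher array, so that IFIT3, IFIT1, PTGS2, NFKBIZ and LIF, the last named after its value was seen, passed through the p53 array alone, and SAMD9 through the control array alone. Over members kept by the mean of the 2 arrays, an alternative chosen after seeing the data, the medians were 0.17 (percentile 99.3) and 0.10 (96.08), the latter inside the central 95%.

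The medians of the metabolic and structural lists lay inside the central 95% of random lists. Of 18 cholesterol synthesis genes, TM7SF2 (1.95) was at least 2-fold higher and CYP51A1 (-1.06) at least 2-fold lower, with IDI1 at 0.80, INSIG1 at -0.79 and a median of -0.20. With the lowess trend removed CYP51A1 stood at -0.92, less than 2-fold. Of 20 glycolysis genes, the hexokinase gene HK2 (-1.44) was the 1 member at least 2-fold lower, with PDK1 at -0.85, PFKM at -0.57, PFKFB3 at 0.53 and a median of -0.15. Of 19 epithelial and mesenchymal genes, the transcription factor gene SNAI2 (2.55) was higher and CLDN1 (-1.05) and ZEB2 (-1.01) were lower, with ZEB1 at -0.89 and a median of 0.00. Equal values in 8 of the 19 hold that median near 0.00. The mean over the probe sets of ZEB2 was -0.88, which is less than 2-fold, as its other probe set stood at -0.75, and CLDN1 was at -0.97 with the lowess trend removed. All 26 ribosomal protein genes lay between RPS23 (-0.16) and RPS19 (0.25), with a median of 0.05.

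Markers of other cell types were mostly below the filter and equal in both arrays. The median of each marker list was 0.00, which the equal values fix, since the random lists of the haematopoietic and fibroblast lists also ran from 0.00 to 0.00. Of 13 haematopoietic markers, 2 were above the filter, CD68 (-0.38) and ITGAM (0.78), and 10 were listed at the same value in both arrays. Of 14 fibroblast and endothelial markers, 2 were above the filter: COL1A1 had the same value in both arrays and ACTA2, the smooth muscle actin gene, was 9.52-fold higher with p53. Of 10 airway and squamous epithelial markers, 3 were above the filter. SCGB1A1, a secretoglobin of airway cells, was 2.71-fold higher with p53, and KRT14 and SCGB3A1 were equal in both arrays.

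**Figure D2:**
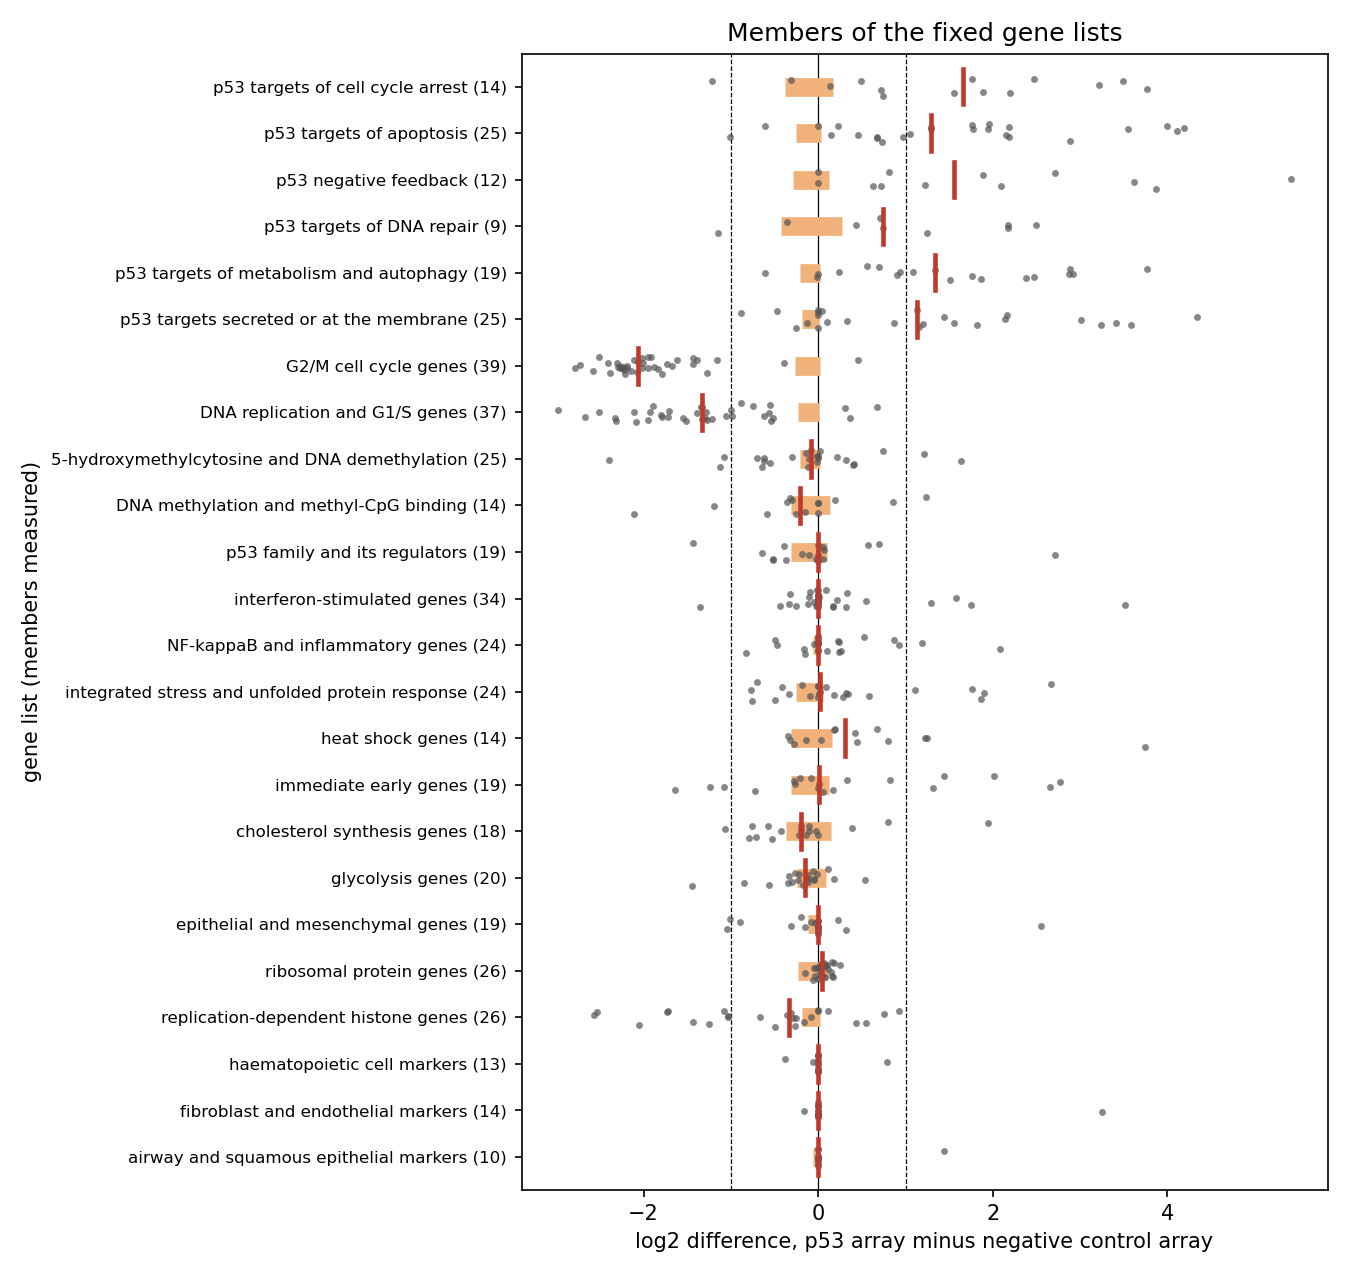
Each grey point is one member of a gene list fixed beforehand, placed by its log2 difference, p53 minus negative control (horizontal axis; vertical jitter has no meaning); the red line is the list median, the orange bar the central 95% of 10000 random lists matched on intensity, and dashed lines mark 2-fold. The medians of the G2/M genes (-2.07) and the DNA replication genes (-1.34) lie far left of their bars, and those of the p53 target lists (0.74 to 1.66) lie right of theirs.

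The size of these differences can be set only against the spread within the 2 arrays. Over the kept genes the median difference was -0.01, and the standard deviation estimated from the median absolute deviation was 0.43 (0.155 with no filter and 0.60 with the filter at the 75th percentile). The ordinary standard deviation of the same differences, which large differences raise, was 0.75. Values were equal in both arrays for 14.6% of the kept genes, which lowers the 0.43. In 65.4% of the kept genes the arrays lay within 0.5 of each other. Where a gene had 2 probe sets of different values above the filter (377 genes), their differences were set against each other. In 2 genes they lay 1 or more apart. The standard deviation between them, estimated from the median absolute deviation and so little affected by large gaps, was 0.11. That spread describes probes read on the same arrays and holds no variation between cultures or hybridisations.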

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

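The tests of explanations in this part were all chosen after the patterns were seen.

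Probe sets that the gene results do not use also differed between the arrays. Among 4236 probe sets without a gene symbol and above the filter, 130 were at least 2-fold higher with p53 than in the control and 113 were lower. Among 1103 probe sets with several symbols and above the filter, 69 were at least 2-fold higher and 53 were lower. In both groups these shares were smaller than among the kept genes, of which 8.21% were higher and 5.79% lower.

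A second pattern lay in the values themselves. In 11947 of 33297 probe sets (35.9%) the 2 arrays held exactly the same value, with 60.8% in the dimmest decile and 3.57% in the brightest decile of probe sets. A single low floor shared by both arrays is argued against, because 19.9% of these equal values lay above the median of all probe sets and the highest was 13.84. The equal values were drawn from 4692 distinct numbers. Only 497 probe sets had a difference other than 0 within 0.01, which is consistent with a summarisation of probes that sets small differences to exactly 0. A difference listed at 0, as for COL1A1 and KRT14, may thus hide a small change. No biological explanation was tested.

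A further pattern was that the largest differences reached further upward (5.62) than downward (-3.01). The 5.62 was that of CLCA2, whose control signal was dim, and from the level of 5.97 its difference was 4.48. A signal floor under the lower genes was tested first by the p53-array level of the 15 lowest genes, whose median of 7.36, against 7.38 for all probe sets, did not decide. In a test set up after that one, 31 genes at a log2 level of 11 or more with p53 were at least 8-fold higher there. By contrast, 1 gene at 11 or more in the control was at least 8-fold lower. Only 1 kept gene was 8-fold lower at any level, so this lower count could not exceed 1. The test thus shows that the pattern also held among bright genes, but it largely restates the pattern and does not decide on a floor. Cells left without p53 in the p53 culture could also limit a fall, since HJURP, the lowest gene, kept 12.4% of its control level, but the share of cells with p53 is not measured by these values, which keeps that explanation open. Slow decay of transcripts made before p53 was present, and a true difference in the strength of induction and repression by p53, stay open as untested.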

How the results depend on the processing

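No paired analysis was possible because each group had 1 array, and no replicate could be left out. The alternatives of 1 planned result that is not reported here were not run. The counts of 939 higher and 662 lower genes stayed within 1.5 times under every alternative except the thresholds: 1.5-fold gave 1642 higher and 1777 lower genes, so that lower genes were the more numerous, and 3-fold gave 450 and 175. The spread of 0.43 fell to 0.155 with no filter and was 0.60 with the filter at the 75th percentile. Of 512 values of the 128 named genes, none changed sign while called and 1 moved, UHRF1 to -1.06 with the mean over its probe sets. A gene value counted as moved when it shifted by more than the spread of 0.43. Centring and the lowess trend shifted kept genes by less than that. The mean over probe sets leaves a gene with 1 probe set as it was, which most named genes are. Most of the 512 values could thus not move, and their number is no measure of stability. Of the 101 named genes at least 2-fold different, 6 values were below 2-fold: those of UHRF2 (-0.99), CYP51A1 (-0.92), CLDN1 (-0.97) and ZEB2 (-0.90) without the lowess trend, and ZEB2 with the mean over probe sets (-0.88) and quantile normalized (-0.98). Genes marked as named after their values were seen were not among the 128, so their calls were not tried under the alternatives. STEAP3 (-1.01) and MBD4 (-1.08), both close to 2-fold, are such genes. Centring added 0.0071 to every difference, quantile normalization moved the median of kept genes by 0.012, and the lowess trend moved single kept genes by -0.22 to 0.15. Of 210 list values, 150 stayed, 60 moved, and none of a list outside the central 95% changed sign. In 204 the list kept its side of the central 95% of random lists, the 6 exceptions being the interferon list over members kept by either filter and by its mean (percentile 98.66), the NF-kappaB list over kept members and without equal genes (98.83), and the heat shock list over members kept by the mean of the 2 arrays (97.475). For the interferon, haematopoietic and fibroblast lists the central 95% of random lists ran from 0.00 to 0.00. There the shift of 0.0071 by centring was enough to count as a move. The cause of the other moves was not tested. Taking the mean of the members gave 1.49 for arrest, 1.54 for apoptosis, 1.91 for feedback, 0.94 for repair, 1.45 for metabolism, 1.19 for secreted, -1.93 for G2/M, 0.20 for interferon, 0.19 for NF-kappaB, 0.31 for integrated stress, 0.56 for heat shock, 0.32 for immediate early, -0.034 for epithelial and mesenchymal, -0.64 for histone, 0.026 for haematopoietic, 0.22 for fibroblast and 0.14 for airway genes. Removing the lowess trend gave 1.43 for apoptosis, 1.69 for feedback, 1.47 for metabolism, 1.24 for secreted, -1.92 for G2/M, -1.26 for replication, 0.0011 for 5hmC, -0.073 for interferon, -0.022 for NF-kappaB, 0.13 for integrated stress, -0.12 for epithelial and mesenchymal, -0.22 for haematopoietic, -0.15 for fibroblast and -0.048 for airway genes. Only kept members gave 1.76 for apoptosis, 1.42 for metabolism, 0.16 for interferon, 0.23 for NF-kappaB, -0.15 for epithelial and mesenchymal and -0.58 for histone genes. The filter on the higher array lets a change decide which dim members are kept. Members kept by the mean of the 2 arrays, an alternative chosen after seeing the data, gave 1.76 for apoptosis, 1.02 for feedback, 1.51 for metabolism, 0.17 for interferon, 0.10 for NF-kappaB, 0.19 for heat shock, -0.15 for epithelial and mesenchymal and -0.58 for histone genes. Members of 1 list only gave 1.66 for feedback, 0.98 for repair and 1.09 for metabolism. Centring gave 0.0071 for interferon, haematopoietic and fibroblast genes. Without genes equal in both arrays, an alternative chosen after seeing the data, the medians were 1.52 for apoptosis, 1.89 for feedback, 1.42 for metabolism, 1.20 for secreted, 0.011 for interferon, 0.23 for NF-kappaB, -0.15 for epithelial and mesenchymal, -0.43 for histone and -0.058 for haematopoietic genes. Equal values in both arrays were more frequent in the dimmest decile of probe sets than in the brightest, which limits what can be read from dim genes.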

Other observations

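The gene groups in this part were listed after the differences had been seen. Their counts, medians, means and percentiles are thus descriptions and not independent evidence. The 2 tests of neighbouring genes were written before their results were seen, and the repeats without histone pairs were chosen afterwards. Of 29 kinetochore and CENP genes, which build the attachment of chromosomes to the spindle, 18 were at least 2-fold lower with p53 and none was higher, with a median of -1.40. HJURP (-3.01), SPC25 (-2.59), CENPI (-2.46) and SKA1 (-2.21) were the lowest of the 29 listed. NUF2 (-2.79), CENPF (-2.41) and CENPE (-2.23), the last 2 named after their values were seen, were not on this list. They were counted above among the G2/M genes, so the count and median do not cover all genes of this kind. Of 21 genes of homologous recombination and the Fanconi anaemia pathway, 11 were at least 2-fold lower and none was higher, with a median of -1.21. RAD51AP1 (-2.83), XRCC2 (-2.80), the Holliday junction resolvase gene GEN1 (-2.38) and UBE2T (-2.27) were the lowest of these.

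In other groups a few members stood apart, so that the median and the mean differed. Among 15 genes of the Notch pathway, the ligand gene JAG2 was 10.6-fold higher, the receptor genes NOTCH3 and NOTCH1 were 5.35-fold and 2.95-fold higher, and NRARP stood at 0.79, while the list median was 0.00. The mean of this list was 0.58, at percentile 99.79 of random lists. Of 27 lysosomal protein genes, 4 were at least 2-fold higher, with CTSH at 5.16, LAMP3 at 4.56 and MANBA at 1.53, and CTSC (-1.38) was lower. The median of the lysosomal list was 0.00 and its mean 0.52 (percentile 99.99), and without genes equal in both arrays its median was 0.15 (97.86). Of 28 genes of the ciliary axoneme, DNAI3 (3.86), CCDC39 (3.53) and CFAP206 (3.39) were the 3 members at least 2-fold higher, RSPH3 stood at 0.80, and 17 were listed at equal values. In the control these 3 stood at 4.97, 4.85 and 5.11, below the 25th percentile of all probe sets (5.97), so the size of their differences rests on a dim signal. The median of the ciliary list was 0.00. From the level of 5.97 their differences were 2.86, 2.41 and 2.53. The mean of the list was 0.40 (percentile 100), which is carried by these 3 genes, seen before the list was drawn up, and its quantile normalized median of 0.00 was at 98.07. Among 8 genes for ligands of the natural killer receptor NKG2D, ULBP1 was 11.8-fold and ULBP2 2.10-fold higher, MICA was 2.30-fold lower and MICB stood at -0.96. The median of this last list was -0.17 over all 8 members and 0.12 over the 7 kept ones, and its mean was 0.28, so its direction is not settled.

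A hypothesis was that genes which differ with p53 lie next to each other on the chromosomes because neighbours share regulation. Neighbours here means next to each other among the kept genes, so genes left out may lie between them. Distances are not given, and some pairs may lie far apart. Among 10820 neighbouring pairs of kept genes, without pairs of like names or identical values, 92 pairs had both genes at least 2-fold higher, against a median of 73 in 10000 random placements of the calls, of which 120 gave as many. For lower genes 66 pairs were found against a median of 36, and no random placement gave as many. Without pairs of 2 histone genes, and with calls shuffled among genes of like intensity, 54 lower pairs remained against a median of 36, and 20 random placements gave as many. The 92 higher pairs stood against a median of 73, and 124 random placements gave as many. ACTA2 (3.25) and FAS (1.76), a death receptor gene, formed one such pair, and STING1 (1.55) and CXXC5 (1.63) another, both chosen after their values were seen. Shared regulation of neighbours may contribute to these excesses. Transcripts that run from one gene into the next, shared promoters, and genes that overlap or lie within one another were not separated from it. The counted pairs included PANK1 with the microRNA gene MIR107, and DLEU2 and DLEU1 each with the microRNA gene MIR15A, all named after their values were seen. Such pairs may read a single locus more than once, which would raise the counts.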
